A study of Arabidopsis thaliana with 12 samples.

How the data were processed

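Total RNA of Arabidopsis thaliana was sequenced from 12 samples in 4 groups of 3: plants labelled heterozygous or homozygous for a T-DNA insertion in DYW2, and plants labelled heterozygous or homozygous for one in NUWA (also called OTP100). Each sample pooled flower bud, rosette and stem, per the labels, and the series description calls the 3 samples of a group biological replicates. The sources used here do not say whether they came from separate plants, and if they did not, p-values measure only the spread between these samples, which may be technical. Libraries were made with a stranded total-RNA kit after depletion of ribosomal RNA, per the labels' protocols.

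The deposited values are whole-number counts of reads per gene model, not normalized, per the file headers. The submitters' processing notes name TopHat2, Bowtie2 and TAIR10, without versions. Reads whose best and second-best alignment scores were equal had been removed before counting, per the file headers, so a gene with an identical copy elsewhere lost its reads. Whether counting used the strand is not given in the sources used here, so overlapping and antisense genes were not separated. In all 12 files the counts summed to the number of counted reads in the header. The totals ranged from 13329334 to 97804029 counts per library. Gene names and positions came from a TAIR10.1 annotation, which matched 32835 of the 33602 gene models. Coordinates are those of TAIR10.1.

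Groups were taken from the sample titles. For 2 libraries the genotype field names the other mutant: dyw2 homozygous replicate 2 is entered there as nuwa homozygous, and nuwa homozygous replicate 3 as dyw2 homozygous. The names of the deposited files call the heterozygous samples wild type. Pairs of replicates were compared by a chi-square of their counts over genes, and its value per degree of freedom lay between 18.2 and 131, so no pair matched within sampling noise.

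Differential expression was tested with edgeR 4.0.16 (R 4.3.3), with the quasi-likelihood F-test, TMM normalization and one model over all 4 groups, which left 8 residual degrees of freedom. Genes were kept by filterByExpr (minimum count 10, minimum total 15), and 21213 were tested. P-values were adjusted by Benjamini-Hochberg, and a gene was called at an adjusted p under 0.05. The 5 contrasts tested were homozygous against heterozygous in each mutant, the difference between these effects, their average, and the difference between both heterozygous groups. No library is shared by the contrasts of the mutants. The groups, tests, 29 gene lists, the rule for named genes and most alternative settings were fixed before the data were examined.

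Gene lists were tested with camera (limma 3.58.1) on log2 CPM (counts scaled to library size, prior count 2) with a preset correlation of 0.01, adjusted over the lists of a contrast. Camera with an estimated correlation and fry were alternatives. The list of seed and embryo genes had fewer than 3 tested members, so 28 lists were tested. Counts of list members in the results are of tested members only, such as 3 of 7 listed mitochondrial and 17 of 23 listed plastid ribosomal protein genes. The 2 genes listed as ccmFN subunits were left out because the annotation contradicted their symbols. Some mitochondrial gene models are pieces of the same gene, such as nad1b and nad1c, and each was counted as a gene. The preset correlation treats such pieces as nearly independent. Of the 15, 14 and 15 lists called for dyw2, nuwa and their difference, none was called with an estimated correlation (4, 5 and 3 at an unadjusted p under 0.05).

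Named genes were DYW2 and NUWA, the 8 nuclear genes with the largest called rise and the 8 with the largest called fall per mutant (mean log2 CPM of at least 1, no overlap between the groups), up to 3 called members of each list per direction or 2 members of a list without calls, and the 5 genes per direction with the smallest p for the difference between mutants. The mean log2 CPM was taken over all 12 libraries, not over the groups compared. Other members named in the text were chosen after their values were seen. Where a group had 0 counts, a fold was computed against a floor of 3 counts over the group and is a bound. With 1 to 3 counts, the ratio is given with its exact 95% counting interval. Bound and interval both pool the reads of a group and hold no spread between libraries.

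Shares of counts from organelle genes left out rRNA and tRNA genes and were compared by exact two-sided permutation tests (scipy 1.17.1).

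The edgeR step was tested on simulated counts with 100 genes changed 2-fold and 100 changed 4-fold. In the dyw2 comparison (20284 genes) 50% and 94% were recovered, and 3 of 147 calls were false. In the nuwa comparison (20290 genes) 54% and 98% were recovered, and 8 of 160 calls were false. The changed genes were not of low counts and went up and down in equal numbers. All other genes had the same mean in every group and were drawn independently. In the data far more genes were called for dyw2, so these rates need not hold there.

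The alternative settings fixed then were DESeq2 size factors, normalization on nuclear genes, no filter or a stricter one (CPM of 1 in 6 libraries), the DESeq2 1.42.0 test, a replicate block, groups from the genotype field, omission of both disputed libraries, an adjusted p under 0.01, omission of rRNA and tRNA genes, a fit of only the groups compared, and omission of each library. Thinning every library to 13329334 counts and a covariate of flower bud markers (mean log2 CPM of the floral organ identity and tapetum lists) were added after the data were seen. Organelle-like stretches of nuclear genes were found with blastn 2.17.0 (at least 95% identity over at least 200 bases, covering at least 50% of the gene).

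The 8 gene families were defined by product names in the annotation after the named genes had been seen. The pattern for mTERF proteins matched 0 tested genes, and that for ribosomal proteins also took those of organelles. That for pentatricopeptide repeat proteins took only genes whose product name gives the family, so it need not hold all members. RNA editing was not analysed here, since counts hold no base changes.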

Results

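The series measured total RNA of Arabidopsis plants with T-DNA insertions in DYW2 or NUWA, which encode pentatricopeptide repeat proteins of organelle RNA editing, to find defects of nuclear and organelle transcripts. There were 3 libraries in each of 4 groups. The libraries labelled dyw2 heterozygous held 54220595, 73060217 and 74179923 counts, those labelled dyw2 homozygous 13329334, 24632485 and 16347805, those labelled nuwa heterozygous 59478718, 97804029 and 74177950, and those labelled nuwa homozygous 68078412, 37496733 and 47062499. For dyw2 homozygous replicate 2 and nuwa homozygous replicate 3 the title and the genotype field name different mutants. The titles were followed here.

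Transcripts of the targeted genes were not reduced in the libraries labelled homozygous. DYW2 (AT2G15690, chromosome 2, 6830995 to 6833777, minus strand, 1 exon, TAIR10.1) had 378, 301 and 404 counts in the libraries labelled dyw2 heterozygous and 306, 558 and 313 in those labelled dyw2 homozygous. After normalization it was 1.6-fold higher (log2 fold change 0.67 ± 0.18 SE, edgeR adjusted p = 0.00561). In the libraries labelled nuwa homozygous DYW2 was 2.06-fold higher than in those labelled nuwa heterozygous (log2 fold change 1.04 ± 0.18 SE, edgeR adjusted p = 0.0148). It was not called without nuwa heterozygous replicate 1 (adjusted p = 0.0627) or 2 (0.0515) or nuwa homozygous replicate 2 (0.0724). NUWA (AT3G49240, chromosome 3, 18255961 to 18258203, plus strand, 1 exon, TAIR10.1) had 30, 24 and 52 counts in the libraries labelled nuwa heterozygous and 32, 40 and 53 in those labelled nuwa homozygous, a log2 fold change of 0.81 ± 0.38 SE that did not pass the test (edgeR adjusted p = 0.269). In the libraries labelled dyw2 homozygous NUWA was 4.07-fold higher than in those labelled dyw2 heterozygous (log2 fold change 2.03 ± 0.36 SE, edgeR adjusted p = 0.00048). Where an insertion lies, and whether transcript beside it is counted, is not given in the sources used here. Every direction below is therefore one between labelled libraries.

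In the libraries labelled dyw2 homozygous, plastid transcripts took a smaller share of the counts and mitochondrial transcripts a larger one. Plastid genes held 30.01% ± 3.07 (SD, n = 3) of counts in them and 61.2% ± 3.50 (SD, n = 3) in those labelled dyw2 heterozygous. Mitochondrial genes held 2.91% ± 0.095 (SD, n = 3) and 0.346% ± 0.035 (SD, n = 3), an 8.41-fold difference. Both differences gave p = 0.1 in exact two-sided permutation tests, the smallest that 3 against 3 allow. Between the nuwa groups the mitochondrial share was 0.539% ± 0.048 (SD, n = 3) in the libraries labelled homozygous and 0.325% ± 0.019 (SD, n = 3) in those labelled heterozygous (exact permutation p = 0.1). Their plastid shares were 62.5% ± 3.73 (SD, n = 3) and 62.9% ± 1.98 (SD, n = 3), a difference within the spread (exact permutation p = 1). Of the libraries whose title and genotype field disagree, dyw2 homozygous replicate 2 had 31.0% plastid and 2.87% mitochondrial counts, beside 26.6% and 32.4% and 3.02% and 2.84% in the others of its title, and nuwa homozygous replicate 3 had 60.5% and 0.587%, beside 66.8% and 60.3% and 0.491% and 0.539%. Over all 12 libraries the mitochondrial share was higher in the 6 labelled homozygous (1.72% against 0.336%, exact permutation p = 0.00216), and the plastid share was 46.3% against 62.1% (exact permutation p = 0.11). Without psbA, the plastid gene with the most counts, the nuwa plastid difference turned to 2.80 percentage points higher in the libraries labelled homozygous (exact permutation p = 0.2). All these shares hold only reads with 1 best position. Reads with equal alignment scores, 6.02% of mapped reads in the libraries labelled dyw2 homozygous and 2.98% in those labelled dyw2 heterozygous, had been removed.

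**Figure D1:**
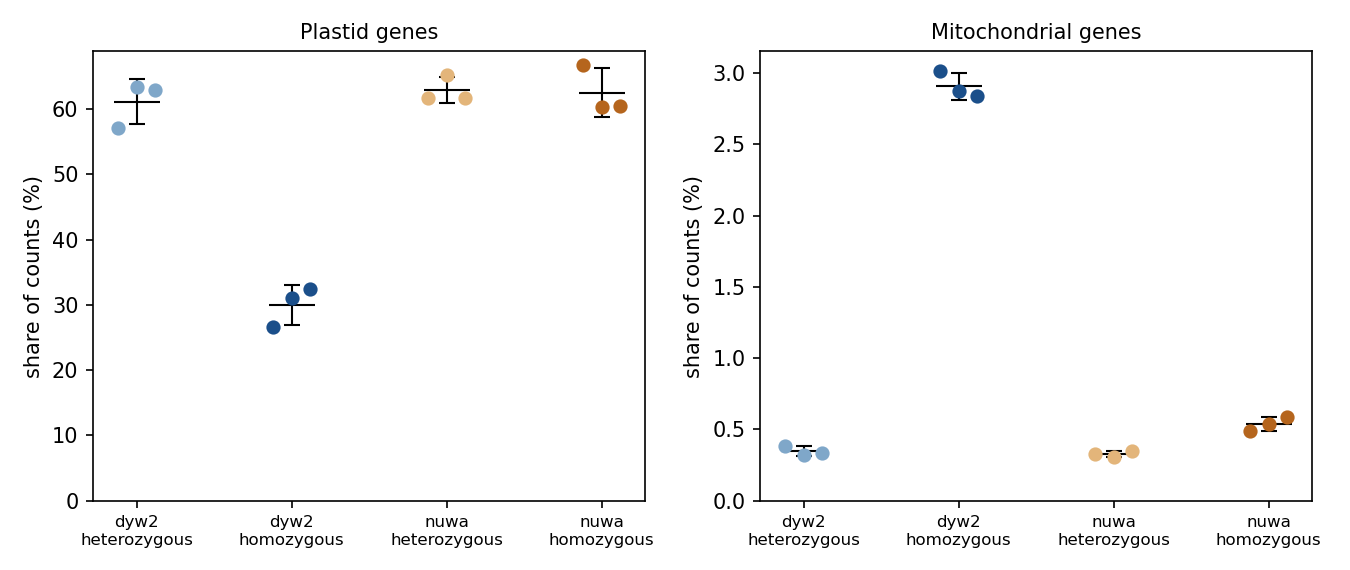
Share of counts (percent) from plastid genes (left) and mitochondrial genes (right) in each of the 12 libraries, as points, with the group mean as a horizontal line and the SD as whiskers. The libraries labelled dyw2 homozygous have a mean of 30.01% for plastid genes and 2.91% for mitochondrial genes.

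Between the libraries labelled dyw2 homozygous and dyw2 heterozygous, photosynthesis transcripts of both the plastid and the nucleus fell, while mitochondrial transcripts and nuclear genes of the mitochondrial stress response rose. All 20 plastid photosystem genes fell (median log2 fold change -2.28), as did all 53 nuclear photosynthesis genes (median -2.75). Of 82 mitochondrial genes tested, 76 rose, with matR, the maturase of mitochondrial introns, 20.2-fold higher. AOX1A, the alternative oxidase that bypasses part of the respiratory chain, rose by 3.42 ± 0.17 (SE) on the log2 scale. In all, 13340 of 21213 genes were called by edgeR, 6376 higher and 6964 lower (5891 higher and 5844 lower with the flower bud score as a covariate). The groups also differed in depth, as given above, and in flower bud markers, whose mean log2 CPM was 3.04, -0.39 and 2.13 in the libraries labelled heterozygous and -2.67, -2.21 and -1.99 in those labelled homozygous.

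Plastid transcripts fell in 82 of 97 genes tested. Among photosystem genes psaJ fell by 3.58 ± 0.32 and psaC by 2.54 ± 0.24 (SE, log2). All 13 genes of ATP synthase, the cytochrome b6f complex and rbcL fell, with atpE at -2.99 ± 0.21 and petN at -3.02 ± 0.28. All 10 tested of 12 listed NDH genes, of the plastid NADH dehydrogenase-like complex, fell, with ndhC at -3.90 ± 0.23 and ndhK at -3.86 ± 0.27. Camera gave adjusted p = 7.8e-08, 1.72e-06 and 3.96e-06 for these 3 lists, and each had adjusted p = 0.365 with an estimated correlation. Of 17 plastid ribosomal protein genes 14 fell, such as rpl33 (-2.84 ± 0.22) and rps16 (-1.90 ± 0.22), and 3 were not called (camera adjusted p = 0.00107, adjusted p = 0.627 with an estimated correlation). Of 6 plastid genes with a promoter of the nuclear-encoded polymerase only accD was called, at -1.17 ± 0.19, and the list did not pass (camera adjusted p = 0.31).

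Nuclear genes for the same organelle fell too. RBCS1B, a Rubisco small subunit, fell 13.3-fold, FNR1 5.94-fold and PSBQ1, a photosystem II subunit, 9.62-fold (photosynthesis list, camera adjusted p = 1.32e-20, adjusted p = 0.365 with an estimated correlation). All 28 nuclear genes of plastid ribosomal proteins fell, such as RPL11 (7.64-fold) and RPS21 (7.43-fold), with camera adjusted p = 3.35e-13 and adjusted p = 0.365 with an estimated correlation. Of 18 tetrapyrrole synthesis genes, of the chlorophyll and heme pathway, 15 fell and 3 were not called, with CHLI2 6.5-fold and DVR 6.25-fold lower (camera adjusted p = 9.92e-06, adjusted p = 0.365 with an estimated correlation). Nuclear genes of plastid transcription went both ways, 5 up and 9 down of 20: the phage-type polymerase genes RPOTMP (6.55-fold) and RPOTP (2.73-fold) rose and the sigma factor genes SIG2 and SIG6 fell (2.67-fold and 2.01-fold, camera adjusted p = 0.477). Of 24 editing factor genes 12 rose, among them MORF1 (5.73-fold) and MORF8 (3.39-fold), and 7 fell, among them DYW1 (5.01-fold, camera adjusted p = 0.154). Of 10 plastid protein quality control genes 2 rose (HSP90.5, CLPC2) and 4 fell, with VIPP1 3.4-fold lower (camera adjusted p = 0.708).

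Among mitochondrial transcripts, 10 of 12 complex I gene models, some of them pieces of the same gene, rose. Examples were nad7 (5.78-fold) and the nad5c exon (5.16-fold), with camera adjusted p = 1.44e-06 and adjusted p = 0.165 with an estimated correlation for the list. Of 8 genes of complexes III, IV and V 7 rose, with cox1 3.58-fold higher (camera adjusted p = 0.00799, adjusted p = 0.365 with an estimated correlation). All 4 tested of 7 listed genes of cytochrome c maturation, matR and mttB rose (camera adjusted p = 0.000462, adjusted p = 0.136 with an estimated correlation). So did the 3 tested of 7 listed mitochondrial ribosomal protein genes, with rps3 11.9-fold and mitochondrial rpl2 5.94-fold higher (camera adjusted p = 0.00276, adjusted p = 0.165 with an estimated correlation). The mitochondrial stress response list had 23 of 25 members higher and 2 lower (camera adjusted p = 4.59e-10, adjusted p = 0.165 with an estimated correlation). UPOX rose 147-fold, the external NADH dehydrogenase gene NDB4 734-fold and the efflux carrier gene DTX3 1360-fold, while the dicarboxylate carrier gene DIC2 fell 14.0-fold and NDA1 1.52-fold. DIC2 was 7.51-fold lower without dyw2 heterozygous replicate 2, and without replicate 3 of that group, which left 3 counts over it, DTX3 had a ratio of 3970 (counting interval 1360 to 19200). Nuclear respiratory chain genes went both ways, 9 up and 5 down of 18, with SDH1-1 of complex II 3.16-fold higher (camera adjusted p = 0.402).

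Markers of flower and stem were lower in the libraries labelled dyw2 homozygous. Of 10 floral organ identity genes 8 fell, with AG 41.5-fold and SEP3 24.2-fold lower (camera adjusted p = 0.0203, adjusted p = 0.627 with an estimated correlation). Of 12 tapetum and pollen wall genes 11 fell (camera adjusted p = 0.0614), and all 5 late pollen genes fell (camera adjusted p = 0.13), with VGD1 at least 282-fold and PPME1 at least 214-fold lower. Without dyw2 heterozygous replicate 1 these bounds were 89.1-fold and 71.8-fold and the late pollen gene VGDH1 was not called (adjusted p = 0.0749), and without dyw2 homozygous replicate 2 they were 156-fold and 118-fold. AG was 73.4-fold lower without dyw2 homozygous replicate 3. Of 13 secondary cell wall genes, which mark stem, 9 fell, with FLA11 5.44-fold lower (camera adjusted p = 0.0246, adjusted p = 0.627 with an estimated correlation). Anthocyanin genes rose in 9 of 13 and fell in 3: MYB90, a regulator of the pathway, rose 20.6-fold and CHS, its entry enzyme, fell 3.79-fold (camera adjusted p = 0.0434, adjusted p = 0.627 with an estimated correlation). MYB90 was 34.1-fold higher without dyw2 heterozygous replicate 2, and the list's median of 4.36 was -0.72 over the 4 members that passed a stricter filter on low counts. Anthocyanin did not pass without dyw2 heterozygous replicate 1 (0.0524) or 2 (0.0569), dyw2 homozygous replicate 2 (0.063) or nuwa heterozygous replicate 2 (0.0613), nor secondary cell wall without dyw2 heterozygous replicate 1 (0.0609) or dyw2 homozygous replicate 1 (0.0535). The tapetum list passed without dyw2 heterozygous replicate 2 (0.00365) or nuwa homozygous replicate 1 (0.0483), 2 (0.0467) or 3 (0.0106), and late pollen without nuwa homozygous replicate 3 (0.0334). Both passed without both disputed libraries (0.0178 and 0.0446), and tapetum also with DESeq2 size factors (0.0499) and after thinning to one depth (0.0469). With the flower bud score as a covariate anthocyanin (0.0883), secondary cell wall (0.238) and complexes III, IV and V (0.0597) did not pass. Anthocyanin did not pass with groups from the genotype field (0.0598), and tapetum (0.0373) and the editing factor genes (0.00575, upwards) did. TT8 had 1 count over the libraries labelled heterozygous and 73 over those labelled homozygous, a ratio of 108 (counting interval 18.8 to 4330), and was at least 23-fold higher without dyw2 heterozygous replicate 3.

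The other lists did not pass camera for dyw2. Senescence and sugar starvation genes had 5 up and 2 down of 10, with SAG13 28.8-fold and ASN1 11.3-fold higher (adjusted p = 0.105, and 0.0394 without nuwa heterozygous replicate 2). Of 12 cold and drought genes 7 fell and 1 rose, with RD22 8.1-fold lower and LTI30 3.77-fold higher (adjusted p = 0.0861, and 0.0322 without dyw2 heterozygous replicate 2). Of 14 jasmonate genes 5 fell, with AOS, of jasmonate synthesis, 9.86-fold lower (adjusted p = 0.31). Of 9 cytosolic heat shock genes 4 rose, with HSP70-4 5.42-fold higher (adjusted p = 0.134). Salicylate and defence genes had 4 up and 2 down of 16, with PR1 7.72-fold higher and ICS1 2.99-fold lower (adjusted p = 0.574), and cell cycle genes 2 up and 3 down of 11, with SMR5 5.93-fold higher (adjusted p = 0.537), their median turning from -0.84 to 0.44, with 4 up, with the flower bud score as a covariate. Fry, which asks whether a list moves one way and not whether it stands apart from other genes, called senescence (0.021), heat shock (0.0118), editing factor (0.00525) and respiratory chain genes (0.0411) upwards and cold and drought (0.00441), jasmonate (0.0258) and late pollen genes (0.0261) downwards. Adjusted over the list alone, 16 plastid ribosomal protein genes, 8 editing factor genes, 6 respiratory chain genes and 9 floral organ identity genes fell, 2 cold and drought genes and 6 senescence genes rose, and all other counts were as given.

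The largest rises among nuclear genes were of OSM34, AT4G25930, AT4G22513, AT2G38380, AT5G54450, NIT2, AT3G05727 and DTX3. OSM34, an osmotin, had 1 count over the libraries labelled heterozygous and 5370 over those labelled homozygous, a ratio of 7960 (counting interval 1430 to 315000). AT4G25930, a DUF295 gene, was at least 669-fold higher, AT4G22513 at least 568-fold, AT5G54450, also DUF295, at least 479-fold and the peroxidase gene AT2G38380 at least 451-fold. Without dyw2 heterozygous replicate 3 these 4 bounds were 427-fold, 362-fold, 305-fold and 288-fold and the ratio of OSM34 was 5080 (counting interval 911 to 201000), and without replicate 2 OSM34 was at least 1800-fold higher. The bound of AT4G22513 was 299-fold without dyw2 homozygous replicate 2 and that of AT2G38380 286-fold without dyw2 homozygous replicate 1. The largest falls were of AT1G66850, XTH3, EXL6, AT4G33355, GRP19, VGD1, AT1G23240 and AT1G68875, with AT1G66850 at least 753-fold, XTH3 at least 601-fold and EXL6 at least 546-fold lower. GRP19, a pollen coat protein gene, went from 7160 counts to 1, a ratio of 4830 (counting interval 866 to 191000). Without dyw2 homozygous replicate 2 the bounds were 417-fold for AT1G66850, 333-fold for XTH3, 302-fold for EXL6 and 891-fold for GRP19, and that of XTH3 was 373-fold without dyw2 heterozygous replicate 3. With groups taken from the genotype field edgeR called 0 genes for dyw2 (5346 at an unadjusted p under 0.05, 1886 by DESeq2).

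**Figure D2:**
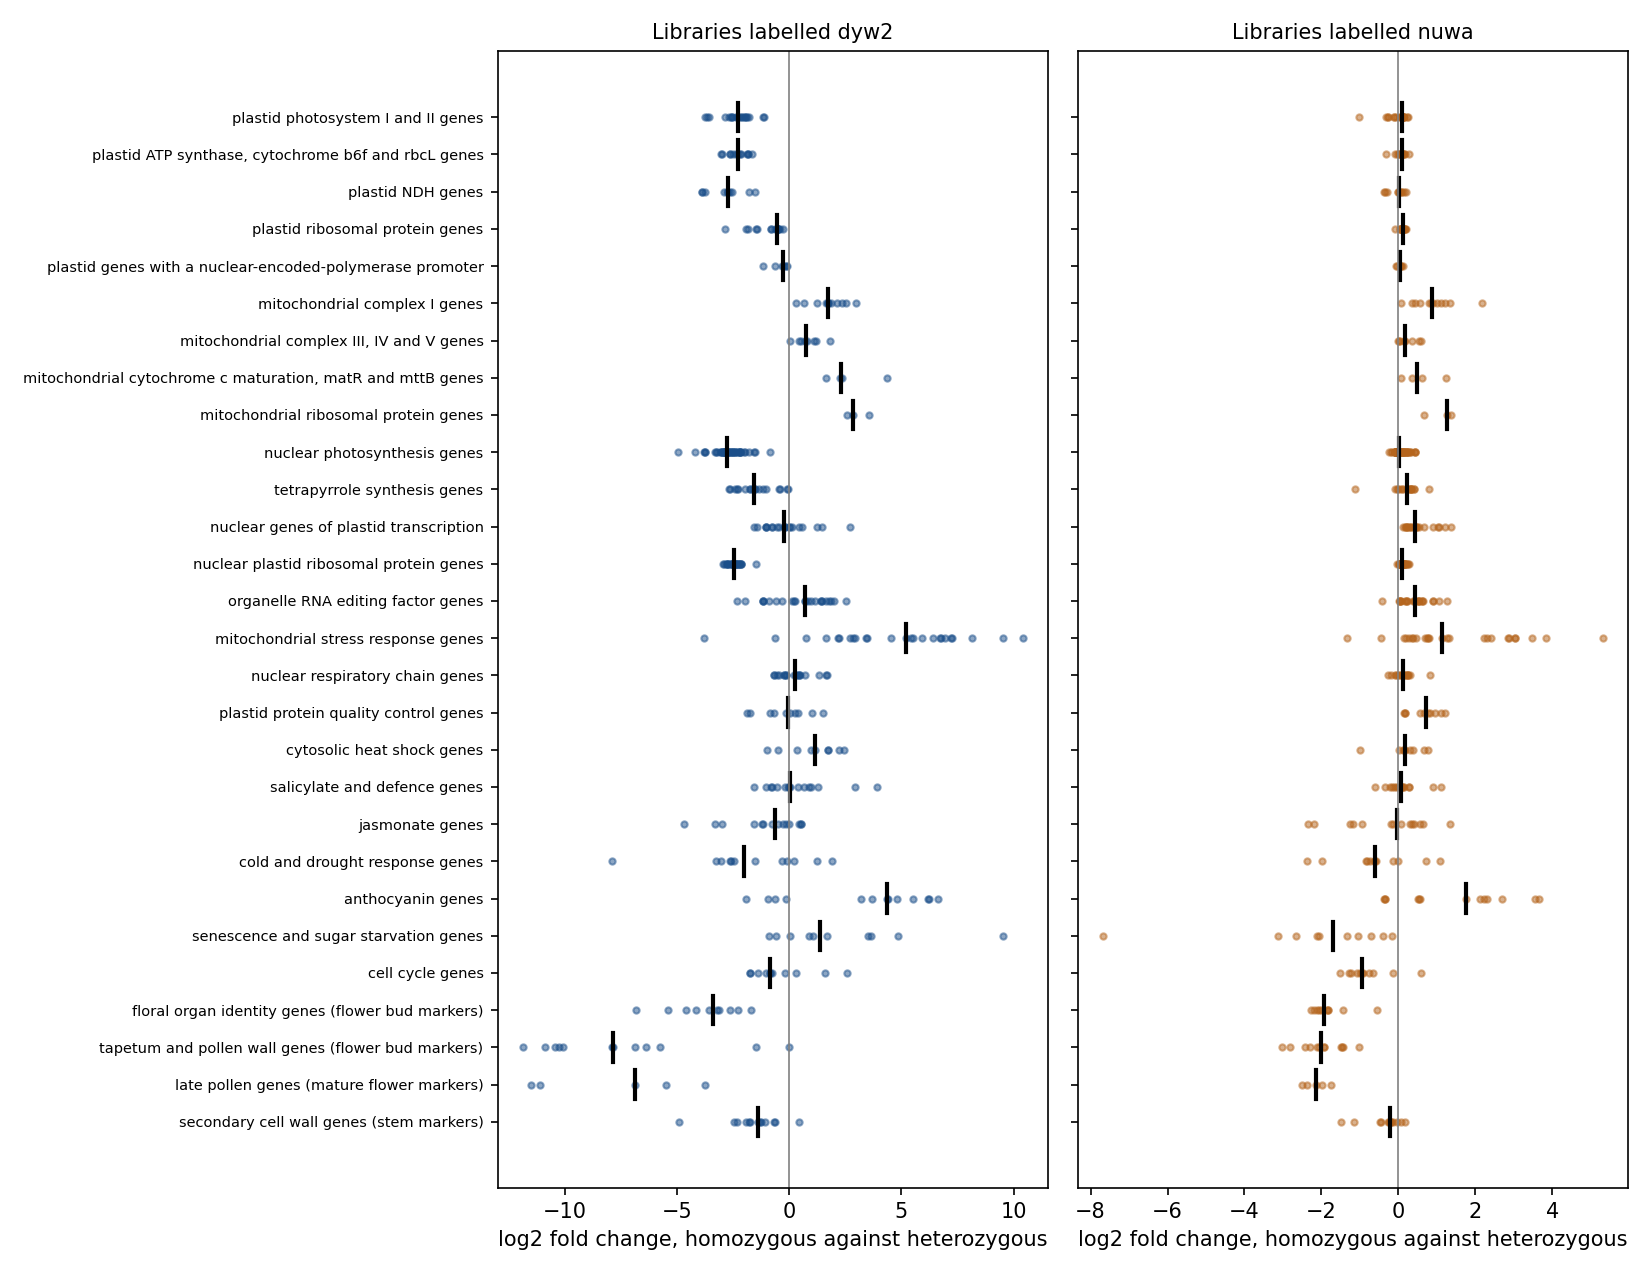
Log2 fold change of each tested list member (points) and the list median (black bar) for homozygous against heterozygous, in the libraries labelled dyw2 (left) and nuwa (right), on axes of different scale. Points of genes with 3 or fewer counts over a group depend on the prior count. The median of the plastid photosystem genes is -2.28 on the left and 0.09 on the right, and that of the mitochondrial stress response genes 5.21 and 1.13.

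Between the libraries labelled nuwa homozygous and nuwa heterozygous, 22 of 82 mitochondrial transcripts and 11 of 25 mitochondrial stress response genes rose, and no plastid transcript was called. DTX3 rose 39.7-fold (61.1-fold without nuwa heterozygous replicate 2), UPOX 8.19-fold, the mitochondrial small heat shock protein gene HSP23.5 14.3-fold and AOX1A by 1.31 ± 0.16 (SE) on the log2 scale. Among the mitochondrial transcripts nad9 of complex I was 4.56-fold higher. Of 97 plastid genes edgeR called 0 (1 at an unadjusted p under 0.05, 0 by DESeq2). In all, 462 genes were called, 327 higher and 135 lower. Without nuwa homozygous replicate 3, or without both disputed libraries, more genes were called lower than higher, as given below. With the flower bud score as a covariate 325 were called, 291 higher and 34 lower, of which 187 were among the 462, and without nuwa homozygous replicate 2 there were 89 higher and 5 lower. Flower bud markers differed within and between the groups, with mean log2 CPM of 2.99, 2.02 and 2.91 in the libraries labelled heterozygous and -2.75, -2.89 and 2.14 in those labelled homozygous.

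Of 12 mitochondrial complex I gene models 6 rose (camera adjusted p = 4.01e-13, adjusted p = 0.0521 with an estimated correlation), with nad1b 2.3-fold and nad5c 2.17-fold higher. All 3 tested mitochondrial ribosomal protein genes rose, with rps3 2.59-fold higher (camera adjusted p = 2.31e-05, adjusted p = 0.0521 with an estimated correlation). So did matR (2.36-fold) and mttB (1.53-fold) of 4 tested genes in their list (camera adjusted p = 0.00112, adjusted p = 0.0521 with an estimated correlation). The mttB call was lost in 8 of 12 omissions of 1 library: dyw2 homozygous replicates 1, 2 and 3 (adjusted p = 0.0501, 0.0504 and 0.0573), nuwa heterozygous replicates 1, 2 and 3 (0.0803, 0.0728 and 0.0995) and nuwa homozygous replicates 1 and 2 (0.0687 and 0.122). Of the ribosomal protein genes, mitochondrial rpl2 was not called without nuwa heterozygous replicate 1 (0.0931), 2 (0.053) or 3 (0.0503) or nuwa homozygous replicate 2 (0.0764), and rpl16 without nuwa heterozygous replicate 2 (0.0574) or 3 (0.0619) or nuwa homozygous replicate 2 (0.0916). Of 8 genes of complexes III, IV and V edgeR called 0 (3 at an unadjusted p under 0.05, 2 by DESeq2), with cox1 at 0.59 ± 0.15 (camera adjusted p = 0.0275, adjusted p = 0.367 with an estimated correlation). In the mitochondrial stress response list 11 of 25 rose (median log2 fold change 1.13, camera adjusted p = 3.88e-15, adjusted p = 0.0521 with an estimated correlation). Without nuwa heterozygous replicate 2 that median was 2.32, or 1.42 with its 4 members near 0 counts at their bound.

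Nuclear genes of plastid transcription had 4 of 20 members higher, among them RPOTMP (2.57-fold), RPOTP (2.33-fold) and FLN1 (2.06-fold, camera adjusted p = 5.22e-09, adjusted p = 0.308 with an estimated correlation). Of 24 editing factor genes 4 rose, among them MORF1 (2.4-fold) and MORF8 (1.57-fold, camera adjusted p = 5.22e-06, adjusted p = 0.129 with an estimated correlation). FLN1 was not called without nuwa heterozygous replicate 3 (0.0509) or nuwa homozygous replicate 2 (0.0512), MORF1 without nuwa heterozygous replicate 1 (0.09), 2 (0.074) or 3 (0.0619) or nuwa homozygous replicate 2 (0.0889), and MORF8 without nuwa heterozygous replicate 1 (0.09) or 3 (0.0727) or nuwa homozygous replicate 2 (0.0738). Of 10 plastid protein quality control genes HSP90.5 alone was called, 2.3-fold higher (camera adjusted p = 2.31e-05, adjusted p = 0.331 with an estimated correlation). Tetrapyrrole genes had 0 of 18 called by edgeR (3 at an unadjusted p under 0.05, 0 by DESeq2, median 0.23, camera adjusted p = 0.0214, adjusted p = 0.697 with an estimated correlation). The tetrapyrrole list did not pass without nuwa heterozygous replicate 2 (adjusted p = 0.128) or nuwa homozygous replicate 1 (0.105) or 2 (0.113), nor did complexes III, IV and V without nuwa homozygous replicate 1 (0.158) or after thinning to one depth (0.0737). By fry neither passed (0.486 for tetrapyrrole, 0.0583 for complexes III, IV and V). Senescence and sugar starvation genes had 3 of 10 lower, DIN1 (8.68-fold), ASN1 (4.19-fold) and DIN10 (2.5-fold), with camera adjusted p = 0.000123 and adjusted p = 0.344 with an estimated correlation. Mean log2 CPM of that list was 2.04, 4.31 and 2.46 in the libraries labelled heterozygous and 1.51, 1.21 and 1.77 in those labelled homozygous. Without nuwa heterozygous replicate 2, the highest, its median went from -1.69 to -0.94 (-0.71 with the member near 0 counts at its bound, camera adjusted p = 0.00541), 2 members were called, with DIN1 4.85-fold lower, and ASN1 was not (adjusted p = 0.113). ASN1 was 6.51-fold lower without nuwa homozygous replicate 3. Without nuwa homozygous replicate 2, DIN1, ASN1 and DIN10 were not called (0.0724, 0.189 and 0.0724). Neither the senescence list (adjusted p = 0.128) nor the tetrapyrrole list (0.526) passed with groups from the genotype field.

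The marker lists of flower and the cell cycle list passed camera for nuwa with 0 members called by edgeR, beside the flower bud scores above. At an unadjusted p under 0.05 there were 4 of 10 floral organ identity genes, 2 of 12 tapetum and pollen wall genes, 0 of 5 late pollen genes and 7 of 11 cell cycle genes, and by DESeq2 2, 0, 0 and 0. The median was -1.94 for floral organ identity genes (camera adjusted p = 6.43e-06, adjusted p = 0.344 with an estimated correlation), -1.997 for tapetum and pollen wall genes (camera adjusted p = 2.31e-05, adjusted p = 0.408 with an estimated correlation), -2.14 for late pollen genes (camera adjusted p = 0.0018, adjusted p = 0.367 with an estimated correlation) and -0.96 for cell cycle genes (camera adjusted p = 0.00112, adjusted p = 0.368 with an estimated correlation). By fry the tapetum (0.0936), late pollen (0.0587) and cell cycle lists (0.0587) did not pass. Mean log2 CPM of the tapetum list was -3.57, -3.43 and 2.06 in the libraries labelled homozygous and 2.96, 1.61 and 2.88 in those labelled heterozygous, so the median lay at the level of no single library. Without nuwa homozygous replicate 3, edgeR called 8 of 10 floral organ identity, 7 of 13 tapetum, 3 of 5 late pollen and 7 of 11 cell cycle genes. The medians were then -6.41, -8.51, -8.93 and -1.68, or -5.29, -6.68, -5.09 and -1.68 with members near 0 counts at their bound. The remaining 14 lists did not pass camera and edgeR called 0 of their members. At an unadjusted p under 0.05 there were 1 photosystem, 3 respiratory chain, 4 jasmonate, 3 cold and drought, 6 anthocyanin and 1 secondary cell wall gene, and by DESeq2 1 respiratory chain, 3 jasmonate and 3 anthocyanin genes. Their adjusted p was 0.995 for photosystem genes, 0.585 for ATP synthase, b6f and rbcL, 0.688 for NDH, 0.179 for plastid ribosomal proteins, 0.731 for genes of the nuclear-encoded polymerase, 0.216 for nuclear photosynthesis and 0.151 for nuclear plastid ribosomal proteins. It was 0.0554 for the nuclear respiratory chain (0.0347 with DESeq2 size factors and 0.0282 with normalization on nuclear genes, upwards), 0.383 for heat shock, 0.216 for salicylate and defence, 0.581 for jasmonate, 0.215 for cold and drought, 0.0609 for anthocyanin and 0.233 for secondary cell wall. Without nuwa homozygous replicate 3, nuclear photosynthesis (0.0021), nuclear plastid ribosomal proteins (1.92e-05), plastid ribosomal proteins (0.00512), ATP synthase, b6f and rbcL (0.0228), the respiratory chain (0.0181) and anthocyanin (0.00641) passed upwards and secondary cell wall (0.0228) downwards, and these 7 passed likewise without both disputed libraries (adjusted p from 2.79e-05 to 0.0284). Without nuwa homozygous replicate 1, photosystem (0.0236) and NDH genes (0.0419) passed downwards and anthocyanin (0.0236) upwards, and without replicate 2 salicylate and defence (0.0357) upwards. Without nuwa heterozygous replicate 1, plastid (0.0318) and nuclear plastid ribosomal proteins (0.0167) and anthocyanin (0.0318) passed upwards and cold and drought (0.0318) downwards, and without replicate 2 the respiratory chain (0.00491) and salicylate and defence (5.27e-06) upwards and secondary cell wall (0.00541) downwards. Anthocyanin also passed without nuwa heterozygous replicate 3 (0.0445) or dyw2 homozygous replicate 3 (0.0495), and the respiratory chain without dyw2 heterozygous replicate 1 (0.0271). Mean log2 CPM of the anthocyanin list was -0.298, 1.53 and -0.579 in the libraries labelled homozygous and -0.559, -0.675 and -0.345 in those labelled heterozygous, and without nuwa homozygous replicate 2 its median went from 1.76 to 0.002 (0.028 with members near 0 counts at their bound, adjusted p = 0.58). Over the 4 members that passed a stricter filter on low counts it was -0.37. With the flower bud score as a covariate photosystem (0.00123), NDH (0.00264), ATP synthase, b6f and rbcL (0.00661), nuclear photosynthesis (0.00388) and nuclear plastid ribosomal protein genes (1.86e-05) passed downwards, and cell cycle (0.684), tetrapyrrole (0.659) and complexes III, IV and V (0.456) did not pass. With groups from the genotype field photosystem (0.0345), nuclear photosynthesis (0.00575) and secondary cell wall genes (0.0103) passed downwards and the respiratory chain (0.0306) and anthocyanin (0.00548) upwards. The photosystem and NDH medians were positive (0.09 and 0.015) and their means negative (-0.02 and -0.05). Adjusted over the list alone, 11 complex I genes, 2 of complexes III, IV and V, 3 of the matR list, 11 of plastid transcription, 6 editing factor, 13 stress response, 5 quality control and 3 anthocyanin genes rose, 3 jasmonate, 7 senescence and 2 floral organ identity genes fell, and all other counts were as given.

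The largest rises among nuclear genes were of 4 DUF295 genes, AT5G54450 (at least 27.6-fold), AT5G52940 (19.5-fold), AT5G54550 (10.3-fold) and AT5G54560 (8.31-fold), and of DTX3, HSP23.5, DTX1 (11.1-fold) and UPOX. AT5G54450 had 0 counts over the libraries labelled nuwa heterozygous and 55 over those labelled nuwa homozygous, beside 969 over those labelled dyw2 homozygous. AT5G54550 had 6 and 46 over the nuwa groups, and AT5G54560 had 7 over the libraries labelled nuwa heterozygous. The minimum mean log2 CPM was taken over all 12 libraries, so AT5G54450 could pass it through the dyw2 libraries. The largest falls were of GLYI4 (20.3-fold), AT2G33830 (10.4-fold), DIN1, AT3G15450 (5.46-fold), BGLU45 (4.54-fold), ASN1, GDPD2 (3.9-fold) and AT3G61160 (3.9-fold). Most of these calls were lost when 1 of the 12 libraries was left out. AT5G54550 kept its call only without dyw2 heterozygous replicate 1 or nuwa homozygous replicate 1 (adjusted p up to 0.116), and AT5G54560 only without dyw2 heterozygous replicate 1 or 2 or nuwa homozygous replicate 1 (up to 0.132). ASN1 (up to 0.189), AT3G61160 (up to 0.162) and GLYI4 (up to 0.15) kept theirs without dyw2 heterozygous replicate 1 or 2, AT3G61160 and GLYI4 also without nuwa heterozygous replicate 3, ASN1 and GLYI4 also without nuwa homozygous replicate 3, and in no other omission. BGLU45 kept its call only without a dyw2 heterozygous library, nuwa heterozygous replicate 3 or nuwa homozygous replicate 3 (up to 0.136), and GDPD2 only without dyw2 heterozygous replicate 1 or 2, dyw2 homozygous replicate 2, nuwa heterozygous replicate 2 or nuwa homozygous replicate 3 (up to 0.152). AT5G54450 was not called without nuwa heterozygous replicate 1 (0.0591), 2 (0.053) or 3 (0.0567) or nuwa homozygous replicate 2 (0.0652), and AT2G33830 not without dyw2 heterozygous replicate 3 (0.0538), dyw2 homozygous replicate 3 (0.0571) or nuwa homozygous replicate 1 (0.0747) or 2 (0.145). DTX1 was not called without nuwa heterozygous replicate 1 (0.0571) or 3 (0.0564), and DIN1 (0.0724) and AT3G15450 (0.0652) not without nuwa homozygous replicate 2. The log2 fold change of AT2G33830 went from -3.38 to -1.94 without nuwa heterozygous replicate 2, where that of DIN1 went from -3.12 to -2.28 and that of BGLU45 from -2.18 to -1.52. GLYI4, at 0 CPM in nuwa homozygous replicates 1 and 2, was at least 27.7-fold lower without replicate 3 of that group, 13.2-fold without replicate 1 and 12.4-fold without nuwa heterozygous replicate 2. DTX1 was 7.17-fold higher without nuwa homozygous replicate 3, and without nuwa heterozygous replicate 2, where 3 counts were left over that group, its ratio was 49.1 (counting interval 16.5 to 241), with DTX3 then 61.1-fold higher. AT5G54550 was 6.45-fold higher without nuwa heterozygous replicate 2 and 5.87-fold without nuwa homozygous replicate 3, and without nuwa heterozygous replicate 1, with 2 counts left over that group, its ratio was 25.4 (counting interval 6.65 to 216). The bound of AT5G54450 was 16.6-fold and 18.3-fold without nuwa heterozygous replicates 2 and 3. Without nuwa homozygous replicate 3 it was 14.3-fold, AT5G54560 was 4.98-fold higher, and ASN1 was 6.51-fold and GDPD2 5.88-fold lower. The count of 462 also depended on single libraries: it was 94 without nuwa homozygous replicate 2 and 1739 (495 higher) without nuwa homozygous replicate 3, and 118, 211 and 157 without nuwa heterozygous replicates 1, 2 and 3, and 253, 282 and 239 without dyw2 homozygous replicates 1, 2 and 3. It was 1411 (387 higher) without both disputed libraries, 0 with groups from the genotype field (3364 at an unadjusted p under 0.05, 1607 by DESeq2), 1422 by DESeq2, 224 after thinning, 60 at an adjusted p under 0.01 and 6 in a fit of the nuwa groups alone.

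**Figure D3:**
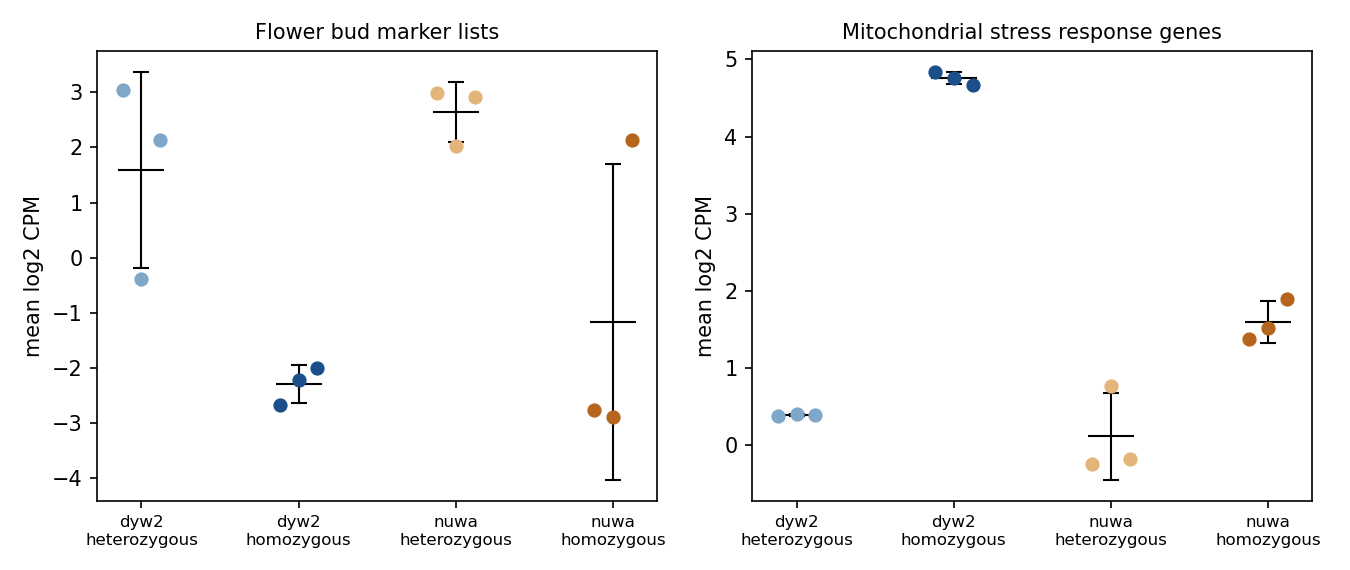
Mean log2 CPM of the flower bud marker lists (left) and of the mitochondrial stress response genes (right) in each of the 12 libraries, as points, with the group mean as a line and the SD as whiskers. The libraries labelled nuwa homozygous lie at -2.75, -2.89 and 2.14 on the left and at 1.38, 1.52 and 1.90 on the right.

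The effects of the mutants differed for 8667 genes in a test of the difference itself, 4074 with a higher and 4593 with a lower effect in dyw2. The balance was 4825 to 4716 without nuwa homozygous replicate 3 and 4863 to 4824 with the flower bud score as a covariate. All 20 plastid photosystem genes and all 53 nuclear photosynthesis genes had a lower effect in dyw2. Of 25 mitochondrial stress response genes 20 had a higher one and 2 a lower one (camera adjusted p = 4.5e-09, 7.25e-27 and 7.66e-08 for these 3 lists, adjusted p = 0.297, 0.296 and 0.296 with an estimated correlation). For AOX1A the difference was 2.11 on the log2 scale (edgeR adjusted p = 4.1e-05). The difference of effect was -0.37 ± 0.25 (SE) for DYW2 (edgeR adjusted p = 0.254) and 1.21 ± 0.52 for NUWA (edgeR adjusted p = 0.0802). With groups from the genotype field edgeR called 0 genes (409 at an unadjusted p under 0.05, 26 by DESeq2).

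Genes called in both mutants mostly moved the same way. There were 359 with the same direction, 293 higher in both and 66 lower in both, and 43 with opposite directions. Independent lists of these sizes would share 98.3 higher, 44.3 lower and 147.9 opposite. UPOX, DTX3, HSP23.5, RPOTMP, RPOTP, MORF1, MORF8 and matR were among those higher in both. Of 271 nuclear genes higher in both with a position in the reference, 31 (11.4%) were mostly covered by sequence like that of the mitochondrial genome, as were 31 of 304 (10.2%) higher for nuwa and 85 of 6287 (1.4%) for dyw2, and values of these genes are uncertain. Across the 21213 genes, which are not independent replicates, the log2 fold changes had Pearson's r = 0.328 and Spearman's rho = 0.278. The count was 88 without nuwa homozygous replicate 2 and 1069 without nuwa homozygous replicate 3, where the balance turned to 352 higher and 717 lower, 95, 179 and 118 without nuwa heterozygous replicates 1, 2 and 3, 207, 232 and 195 without dyw2 homozygous replicates 1, 2 and 3, 864 (289 higher and 575 lower) without both disputed libraries and 0 with groups from the genotype field (555 by DESeq2).

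Averaged over both mutants, 11422 genes were called, 4937 higher and 6485 lower in the libraries labelled homozygous. Of these, 72 of 97 plastid genes were lower and 70 of 82 mitochondrial genes higher. The average does not show that a gene moved in both mutants: in each mutant alone 82 and 0 plastid genes were called lower by edgeR (dyw2 and nuwa, 0 for nuwa by DESeq2 and 1 at an unadjusted p under 0.05) and 76 and 22 mitochondrial genes higher, and the effects differed for 77 plastid and 64 mitochondrial genes. DYW2 was 1.81-fold and NUWA 2.67-fold higher (edgeR adjusted p = 0.000181 and 0.000884). With groups from the genotype field the count was 3046 and the balance turned to 1863 higher and 1183 lower. Both groups labelled heterozygous differed in 28 genes, 6 higher and 22 lower in those labelled dyw2. That count was 18 without dyw2 heterozygous replicate 2, 115 without nuwa heterozygous replicate 2, where the balance turned to 92 higher and 23 lower, 161 by DESeq2 (101 higher and 60 lower) and 0 with groups from the genotype field (408 at an unadjusted p under 0.05, 24 by DESeq2). The genotype field leaves both heterozygous groups as they are, so that 0 came through the spread shared by all groups in the model.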

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

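The tests of depth, normalization, overall plastid RNA, disputed genotypes and the flower bud covariate were chosen after the results were seen, and that of mitochondrial copies in the nucleus before its result was seen.

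The effect of the mutants differed in a test of the difference itself for 8667 genes and for 15 gene lists, 0 of which camera called with an estimated correlation (adjusted p from 0.125 to 0.626, 3 at an unadjusted p under 0.05). The median difference of the log2 fold changes, dyw2 minus nuwa, was -2.41 for plastid photosystem genes, -2.31 for ATP synthase, cytochrome b6f and rbcL, -2.76 for NDH genes, -0.68 for plastid ribosomal proteins, -2.78 for nuclear photosynthesis genes, -1.59 for tetrapyrrole synthesis, -0.64 for nuclear genes of plastid transcription, -2.59 for nuclear plastid ribosomal proteins and -0.86 for plastid protein quality control. It was 1.199 for mitochondrial complex I, 0.58 for complexes III, IV and V, 1.83 for cytochrome c maturation, matR and mttB, 1.91 for mitochondrial ribosomal proteins, 2.73 for mitochondrial stress response genes (3.40 with its 2 members near 0 counts at their bound) and 3.88 for senescence and sugar starvation genes. Plastid protein quality control did not pass without dyw2 heterozygous replicate 1 (camera adjusted p = 0.165) or 2 (0.0953), dyw2 homozygous replicate 1 (0.148) or 2 (0.0597), nuwa heterozygous replicate 1 (0.0794), 2 (0.146) or 3 (0.0593), or nuwa homozygous replicate 2 (0.157) or 3 (0.119). Complexes III, IV and V did not pass without dyw2 heterozygous replicate 1 (0.0914), nuwa heterozygous replicate 3 (0.054) or nuwa homozygous replicate 3 (0.0964). With groups from the genotype field 6 of the 15 did not pass: mitochondrial stress response (0.103), complex I (0.217), complexes III, IV and V (0.234), cytochrome c maturation, matR and mttB (0.152), mitochondrial ribosomal proteins (0.142) and plastid protein quality control (0.0554). Cell cycle (0.0072), floral organ identity (0.00151), tapetum (1.04e-05) and late pollen genes (0.00225) then passed with a higher effect in dyw2. Without both disputed libraries complexes III, IV and V (0.0752) and plastid protein quality control (0.0854) did not pass. Secondary cell wall passed with a lower effect in dyw2 without dyw2 heterozygous replicate 3 (0.017), dyw2 homozygous replicate 3 (0.0376), nuwa heterozygous replicate 3 (0.0192) or nuwa homozygous replicate 1 (0.0389) or 2 (0.0376), cold and drought likewise without dyw2 heterozygous replicate 2 (0.0301) or nuwa heterozygous replicate 2 (0.0287), and anthocyanin with a higher one without nuwa homozygous replicate 2 (0.00366).

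The genes with the smallest p for that difference were SCPL7 (4.85), AT2G20720 (4.85), AT2G07677 (3.68), AT2G07686 (2.79) and AT3G22850 (2.40) with a higher effect in dyw2, and AT5G22390 (-5.69), NdhU (-5.36), IAA5 (-5.15), SOFL2 (-5.14) and AT5G12940 (-4.35) with a lower one, all on the log2 scale. Reads removed by the authors for mapping equally well to several places, which no comparison used, made up 6.02% of mapped reads in the libraries labelled dyw2 homozygous, against 2.98% in those labelled dyw2 heterozygous.

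Plastid photosynthesis genes were lower in the libraries labelled dyw2 homozygous, which were also the shallowest and had the lowest plastid share. The tables argue against a lower level of all plastid RNA, a scaling of whole libraries and the disputed genotypes as the whole cause. Thinning and normalization on nuclear genes could not by themselves decide on depth or normalization. Thinning leaves the expected fold of abundant transcripts as it was, and 21034 of the 21213 genes under TMM were nuclear already. The median of the plastid photosystem I and II genes was -2.28 when every library was thinned to one depth, -2.28 with normalization on nuclear genes and -2.21, with all 20 called, without both disputed libraries, which in 8 of 8 values (organelle shares, photosystem genes and stress response genes in each) lay closer to the other homozygous libraries of their title than to those of the mutant their genotype field names, by more than the spread. Less plastid RNA of every kind, or a scaling of whole libraries by depth or normalization, would leave the ratio between plastid genes alone. The log2 difference between genes of the nuclear-encoded polymerase and photosystem genes moved by 1.92, with no overlap of the libraries. It was -1.92, -2.09 and -2.38 in the libraries labelled dyw2 heterozygous and -0.08, -0.31 and -0.25 in those labelled homozygous. These values argue against such scaling as the whole cause, though not on the exact size of the fall. A lower level of these transcripts tied to the dyw2 label stays open as a hypothesis, beside organ mix. With the flower bud score as a covariate the median was -2.80. That score did not overlap between the dyw2 groups, so the covariate cannot set flower buds aside.

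AT2G07677 and AT2G07686 are covered over their whole length by sequence like that of the mitochondrial genome. A candidate explanation is that reads of mitochondrial transcripts were counted at nuclear copies: of 89 nuclear genes mostly covered by mitochondrial-like sequence, 85 rose in dyw2 (95.5%), against 29.7% of 20914 other nuclear genes. For nuwa 31 of the 89 rose (34.8%), against 1.3% of the others. Transcription of the nuclear copies themselves was not tested, so values of these genes are uncertain.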

How the results depend on the processing

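Thinning and the flower bud covariate were chosen after the data were seen. The counts for dyw2 (13340), for the difference between mutants (8667) and for the average (11422) stayed within 1.5 times under all alternatives run except those named here. With groups from the genotype field edgeR called 0 genes for dyw2, nuwa, their difference, both mutants together and the heterozygous groups, and 3046 for the average, with the balance turned (43.2% higher to 61.2%). At an unadjusted p under 0.05 edgeR then had 5346, 3364, 409 and 408 for dyw2, nuwa, the difference and the heterozygous groups, and DESeq2 1886, 1607, 26 and 24 (both mutants 555). At an adjusted p under 0.01 the counts were 60 for nuwa, 5496 for the difference, 59 for both mutants and 18 for the heterozygous groups. DESeq2 called 1422 for nuwa, 968 for both mutants and 161 for the heterozygous groups, 62.7% of them higher in those labelled dyw2 (21.4% by edgeR, 80.0% without nuwa heterozygous replicate 2). With the flower bud covariate nuwa had 325, of which 187 were among the 462. Without both disputed libraries nuwa had 1411 and both mutants 864, in a fit of only the groups compared 6 and 6, and after thinning 224 and 177. Omission of 1 library gave 94 to 1739 for nuwa, 88 to 1069 for both mutants and 18 to 115 for the heterozygous groups. The genotype field leaves both heterozygous groups as they are, so their fall from 28 calls to 0 came through the spread shared in the model. That shared spread enters the other counts with this grouping too. Without nuwa homozygous replicate 3, or without both disputed libraries, most nuwa calls were lower. Apart from these points and from fewer samples or genes, the cause was not tested.

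With the replicate block nuwa had 183 calls and both mutants 157. Samples sharing a number did not deviate together more often than others: 4 of 18 pairs with the same number had a correlation over 0.1, against 7 of 36 other pairs. This gives no sign of pairing by number, but with 3 libraries a group it cannot rule pairing out. With the block the tapetum list passed for dyw2 (camera adjusted p = 0.0292) and anthocyanin for nuwa (0.0492).

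With an estimated correlation 0 lists were called for dyw2, nuwa and their difference (4, 5 and 3 unadjusted), and fry called 9 for nuwa. DYW2 and NUWA lost their dyw2 calls with groups from the genotype field, at 0.81 and 1.73. DYW2 lost its nuwa call there (0.91), in a fit of only the nuwa groups (1.03) and without nuwa heterozygous replicate 1 (1.04) or 2 (0.96) or nuwa homozygous replicate 2 (0.996), with a range of 0.89 to 1.22 over all omissions. Of 163 called values of named genes, 163 lost their call with groups from the genotype field, 22 with the flower bud covariate and, of 149 tested there, 26 in a fit of only the groups compared. The replicate block lost 14 of 163, and thinning 12 of 162. Omission of 1 library lost from 3 (dyw2 heterozygous replicate 1, nuwa homozygous replicate 3) to 20 (nuwa homozygous replicate 2).

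Named genes kept their direction under all alternatives run except the following. With the flower bud covariate KNOLLE in dyw2 went from -1.74 to 0.00 (0.004). In nuwa, with groups from the genotype field, GLYI4 went to 1.91, BGLU45 to 2.61, ASN1 to 1.11, psaA to -0.054, rbcL to -0.075, accD to -0.13, PSAD2 to -0.028, RPL12-C to -0.034 and RPL27 to -0.066. With the flower bud covariate rbcL went to -0.06, rpl14 to -0.12, rps4 to -0.17, rpoC2 to -0.10, accD to -0.29, RPL12-C to -0.15 and RPL27 to -0.18. With 1 library left out rpoC2 ranged from -0.01 (without nuwa heterozygous replicate 2) to 0.22, and accD from -0.15 (without nuwa homozygous replicate 1) to 0.21. Except KNOLLE, GLYI4, BGLU45 and ASN1 none of these was called to begin with, and the cause was not tested.

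The nuwa plastid share difference turned from -0.363 to 2.80 percentage points without psbA, 0.656 without both disputed libraries and up to 0.779 with 1 library left out (lowest -2.51). The pooled difference ranged from -19.9 (without nuwa homozygous replicate 1, exact permutation p = 0.0303) to -11.8 with 1 library left out. At the shallowest library's depth dyw2 had 11369 calls (13340 as deposited) and nuwa 224 (462).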

Other observations

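Tests of gene families, of the disputed genotypes, of the flower bud covariate, of depth and of an estimated correlation without the disputed libraries were chosen after the results were seen, and the counts over other splits of the samples before. DUF295 genes were among the largest rises named above, so the test of that family is not independent of them.

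Genes of pentatricopeptide repeat proteins, the family of DYW2 and NUWA, were more often higher than lower in the libraries labelled dyw2 homozygous. Over all 21034 nuclear genes tested, 6300 rose and 6882 fell for dyw2, and 305 rose and 135 fell for nuwa. Of 241 genes of the family, 131 rose and 31 fell for dyw2 (camera adjusted p = 7.98e-06, adjusted p = 0.235 with an estimated correlation). For nuwa 5 rose, too few calls to set the family apart from the nuclear genes (camera adjusted p = 7.21e-13, adjusted p = 0.123 with an estimated correlation). Those 5 calls were lost without any 1 of the nuwa heterozygous libraries or nuwa homozygous replicate 2, and 1, 2 and 2 were called without dyw2 homozygous replicates 1, 2 and 3, and 9 without dyw2 heterozygous replicate 1 or nuwa homozygous replicate 3. Of 25 DUF295 genes 13 rose and 3 fell for dyw2 (camera adjusted p = 0.0101, adjusted p = 0.196 with an estimated correlation), and 5 rose for nuwa (camera adjusted p = 0.398, upwards, with a median of -0.09, and 0.0375 with the flower bud score as a covariate). That count was 2 without any 1 of the nuwa heterozygous libraries or nuwa homozygous replicate 2, 3 without a dyw2 homozygous library or dyw2 heterozygous replicate 3, 3 higher and 4 lower without nuwa homozygous replicate 3, and 3 and 3 without both disputed libraries. Of 48 histone genes 34 fell and 4 rose for dyw2 (camera adjusted p = 1.62e-05, adjusted p = 0.196 with an estimated correlation), and 6 fell for nuwa (camera adjusted p = 7.21e-13, adjusted p = 0.0633 with an estimated correlation). Flower bud markers were at -2.75, -2.89 and 2.14 log2 CPM in the libraries labelled nuwa homozygous and at 2.99, 2.02 and 2.91 in those labelled nuwa heterozygous, and at -2.67, -2.21 and -1.99 against 3.04, -0.39 and 2.13 for dyw2. The cell cycle list had a median of -0.96 for nuwa and did not pass with the flower bud score as a covariate (0.684). With that covariate 28 histone genes fell and 3 rose for dyw2 (camera adjusted p = 0.000131), and the list passed for nuwa (camera adjusted p = 2.22e-07, median -0.31 against -0.48), but the 6 calls were lost, as they were without nuwa heterozygous replicate 1 or 3 or nuwa homozygous replicate 2. There were 1 without nuwa heterozygous replicate 2, 2 without dyw2 homozygous replicate 1 or 3 and 13 without nuwa homozygous replicate 3 or without both disputed libraries. With DESeq2 size factors and with normalization on nuclear genes the medians of these families kept their sign in both mutants.

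Among 191 ribosomal protein genes 58 rose and 33 fell for dyw2 (camera adjusted p = 0.141), and 2 rose for nuwa (camera adjusted p = 7.77e-08, adjusted p = 0.4 with an estimated correlation), 1 without nuwa heterozygous replicate 1 or 3 or nuwa homozygous replicate 2, 6, with 2 lower, without nuwa homozygous replicate 3, and 4, with 2 lower, without both disputed libraries. MATE efflux, glutathione S-transferase and UDP-glycosyltransferase genes did not pass for dyw2 (camera adjusted p = 0.0607, 0.0638 and 0.208) or for nuwa (0.201, 0.577 and 0.931). For dyw2 MATE and glutathione S-transferase genes passed upwards without dyw2 heterozygous replicate 3 (0.0353 for both), nuwa heterozygous replicate 1 (0.0473 for both) or nuwa heterozygous replicate 2 (0.0398 and 0.0281), and for nuwa glutathione S-transferase genes did without nuwa heterozygous replicate 2 (0.0137).

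The libraries of disputed genotype were compared with the others by the correlation of log2 CPM across genes. Replicate 2 labelled dyw2 homozygous had 0.984 and 0.986 with the other libraries of that title and 0.828, 0.849 and 0.841 with those titled nuwa homozygous. Replicate 3 labelled nuwa homozygous had 0.946 and 0.952 with the other libraries of its title, 0.816, 0.841 and 0.851 with those titled dyw2 homozygous, and more with the libraries labelled heterozygous: 0.977, 0.971 and 0.975 with dyw2 and 0.961, 0.964 and 0.974 with nuwa. Its flower bud score of 2.14 also lay with theirs, while its mitochondrial share of 0.587% and its mean of 1.90 log2 CPM for mitochondrial stress response genes lay above those of all 6 heterozygous libraries (at most 0.386% and 0.769) and beside the 0.491% and 0.539% and the 1.38 and 1.52 of its title. For dyw2 homozygous replicate 2 that mean was 4.76, beside 4.84 and 4.67 in the others of its title. As an exchange between the homozygous groups, the genotype field is thus argued against by the values of both libraries, if the other titles are right.

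Of 25 mitochondrial stress response genes 11 were called higher in the libraries labelled nuwa homozygous (camera adjusted p = 3.88e-15, adjusted p = 0.0521 with an estimated correlation), of which replicates 1 and 2 had low flower bud markers. The median log2 fold change of 1.13 was 1.19 with the flower bud score as a covariate and 1.096 at one depth. Neither value decides. The slope of the covariate rested mostly on nuwa homozygous replicate 3 and dyw2 heterozygous replicate 2, whose scores stood apart in their groups. Thinning leaves the expected fold as it was. Replicate 3 labelled nuwa homozygous, with a score of 2.14, had a stress response mean of 1.90 log2 CPM, beside 1.38 and 1.52 in replicates 1 and 2. Without both disputed libraries the median was 0.81, with 11 members called (camera adjusted p = 2.35e-10, adjusted p = 0.175 with an estimated correlation), and without nuwa heterozygous replicate 2 it was 2.32 (1.42 with members near 0 counts at their bound). An effect tied to the nuwa label stays open as a hypothesis, beside depth and organ mix, flower buds included.

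Other splits of the libraries were counted for each comparison. For dyw2 the real split called 13340 genes, for nuwa 462 and for both groups labelled heterozygous 28, and the highest of the 9 other splits called 0 by edgeR in each case (at most 555, 2901 and 2333 at an unadjusted p under 0.05). In each, 1 of 10 splits gave as many, and 10 splits are too few for a share under 0.05. For the average over both mutants 1 of 100 splits gave 11422 or more, with 10820 as the highest other. In both drawn sets each of the 11 other splits with any call had the 3 libraries of each dyw2 group together, on opposite sides. The count for the average thus mostly follows the gap between the dyw2 groups, for which 10 splits are too few. It does not exclude chance for an effect in both mutants. For the difference between mutants 9 of 100 splits gave 8667 or more, up to 11422, so chance is not excluded by this count. That highest split exchanged both nuwa groups and left the dyw2 groups as they are, so the count follows a structure of the samples, the gap between the dyw2 groups.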
